A study of Mus musculus with 6 samples.

How the data were processed

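The samples were 6 libraries of polyadenylated RNA from whole mouse brain: 3 immunoprecipitated with an antibody against N6-methyladenosine (m6A IP 1, 2 and 3) and 3 of input RNA, made without antibody. Per the labels' protocols, total RNA was extracted with TRIzol, and polyadenylated RNA was isolated with a Dynabeads mRNA DIRECT kit. The series' design text names stranded TruSeq mRNA libraries. Groups and replicate numbers were taken from the sample titles.

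The deposited files were 3 peak lists, each made from 1 IP library and 1 input library. Per the submitters' processing notes, the tools included TopHat2 2.1.0 and MACS2 2.1.0, and the genome build was mm9. Peaks were called separately in each replicate with MACS 2.1.0.20151222, per the file headers, with a q-value cutoff of 0.05 and an effective genome size of 1.87e+09 bases. Per the file headers, tags were extended to 50 bases with no fragment model, at most 1 tag was kept per position, the larger library was scaled to the smaller, and local background was taken over 1000 and 10000 bases. The order in which TopHat2 and MACS2 were run, and the alignment settings, are not given in the sources used here. The headers also carry a run name with the letters ctl whose meaning the labels do not explain, and no genotype was assumed from it.

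The pileup is a coverage signal, the highest number of IP tags over a base of the peak, deposited by the authors without further scaling because the IP was the smaller library in each replicate. The fold enrichment is the authors' own ratio of IP pileup to local input background at the peak summit, and the strength of a peak was deposited as −log10 p-value and −log10 q-value. The other deposited columns were positions and lengths in bases. Folds and q-values were used only to describe, rank or filter peaks. The local input background was recovered from the deposited pileup and fold, taking the fold as (pileup + 1) / (background + 1). A Poisson p-value computed from the recovered background differed from the deposited −log10 p-value by at most 6.71e-05 in any replicate. Divided by the input scaling factor of 0.763, 0.560 or 0.881, the background was a whole number of input tags, within 0.01, for 63.6%, 68.8% and 61.8% of peaks in m6A IP 1, 2 and 3. For the remaining peaks the background was taken to come from a wider window or from the genome average.

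Every coordinate is 1-based on mm9, as in the deposited lists. No peak ended beyond an mm9 chromosome, and 233, 228 and 172 peaks of the 3 lists ended beyond the corresponding mm10 chromosome. The gene annotation at hand was on GRCm38 (mm10), so no coordinate was compared with it. The lists carried no gene names and no strand. Genes, exons, UTRs and sequence motifs are therefore not reported, and the planned tests of 16 fixed gene lists, of genes with a peak in all 3 replicates and of transcript position were not run.

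Peaks of the 3 replicates that shared at least 1 base were merged into regions, and a region counted as found in all 3 replicates if it held a peak of each. The share of peaks overlapping another replicate was compared with the same share after that replicate's peaks had been moved 5000 bases in either direction. Rank agreement was Spearman's rho across regions with peaks in both replicates, using the highest fold of the region. Regions are not independent replicates, so no p-value was given. These steps were fixed before the data were examined. So was a rule to name the 10 genes whose region had the highest mean within-replicate percentile of fold. Its use for regions in place of genes was decided after seeing the data. Clusters of regions (gaps of at most 1000 bases), the 5 longest regions, the 5 with the highest mean pileup, chromosome densities, 1 Mb windows and input levels were chosen after seeing the data. Alternatives changed the peak threshold, the required overlap, the number of replicates required, the shift and the gap, and left out each replicate in turn. The fold, pileup and input background of a region in a replicate were each the highest among its peaks, taken separately. They can come from different peaks, so a region's background is not always the one behind its fold.

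Shares carry 95% Wilson intervals and pileups 95% exact Poisson intervals. Both cover counting error only. Nothing in the labels says that the 3 replicates came from separate animals, so the SDs may be technical. The lists differed in tag totals and in peaks, so no replicate was a copy of another. All samples were of 1 tissue, and no 2 conditions could be compared. Region merging was tested on simulated lists of 25000 peaks per replicate, where 14994 regions were found in all 3 lists against 15000 planted. The planted sites lay at random along the chromosomes, so merging among close neighbours, as in the real lists, was not tested. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and GenomeInfoDb 1.38.1, the last for chromosome lengths.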

Results

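The series concerns the place of mRNA methylation in the maturation of oligodendrocytes, the myelin-forming cells of the central nervous system. The deposited peak lists mapped N6-methyladenosine (m6A), an internal methylation of adenosine in messenger RNA, across polyadenylated RNA of whole mouse brain by m6A-seq, in which RNA bound by an m6A antibody is sequenced beside input RNA. There were 3 IP libraries and 3 input libraries, each IP set against 1 input. The IP libraries held 16764956, 18489297 and 17333767 tags in m6A IP 1, 2 and 3, of which 5676427, 6493926 and 6327958 remained after the authors' removal of duplicates. The matching inputs held 21820721, 36372297 and 21529770 tags, of which 7436658, 11589632 and 7185922 remained. All samples were of 1 tissue with no second condition, so the comparisons are between replicates, between IP and input as the peak caller made them, and between parts of the genome. The lists gave positions on mm9 without gene names or strand, and the genes, exons and UTRs at these positions are not given here.

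Short segments of brain RNA were enriched over input in each IP. There were 32858 peaks in m6A IP 1, 32671 in m6A IP 2 and 24686 in m6A IP 3, a mean of 30072 ± 4665 (SD, n = 3). Peaks covered 4483, 4439 and 3017 kb of the genome. Their median length was 101, 101 and 94 bases, and the longest peak was 1702 bases. The median fold enrichment, the authors' own value, was 4.64 ± 0.127 (SD, n = 3) over the 3 lists, with a lowest fold of 1.60 and a highest of 30.4 in any list. A typical peak rested on few tags: the median pileup was 19, 21 and 19 IP tags, and a count of 19 has a 95% exact Poisson interval of 11.4 to 29.7. Intervals cover counting error only. Peak number was sensitive to the threshold: with a −log10 q of at least 10, the lists held 7502, 7198 and 3766 peaks.

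The question of which enriched segments recur across brain libraries was addressed by merging peaks of the 3 lists that shared at least 1 base. This gave 43377 regions, of which 16757 were found in all 3 replicates, 38.6% (Wilson 95% interval 38.2 to 39.1). A further 9789 regions (22.6%, interval 22.2 to 23.0) were found in 2 replicates and 16831 (38.8%, interval 38.3 to 39.3) in 1. Regions found in all 3 replicates covered 3730 kb, with a median length of 185 bases. A merged region is longer than its peaks by construction, so lengths were compared between single peaks: those in regions found in all 3 replicates had a median of 143, 141 and 110 bases in m6A IP 1, 2 and 3, against 65, 65 and 60 bases for peaks found in 1 replicate. A longer peak is more likely to share a base with a peak of another list, so the overlap rule may set part of this difference. Among regions in 2 replicates, 6597 were shared by m6A IP 1 and 2, against 1632 by m6A IP 1 and 3 and 1560 by m6A IP 2 and 3. Of single-replicate regions, 6860 came from m6A IP 1, 6809 from m6A IP 2 and 3162 from m6A IP 3. The number found in all 3 fell to 8111 with a fold of at least 4, to 11128 with a reciprocal overlap of at least 50% and to 2057 with a −log10 q of at least 10. It rose to 26546 when 2 replicates were enough.

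Peaks of regions found in all 3 replicates stood apart from single-replicate peaks in height more than in fold. Their median pileup was 24, 25 and 22 tags in m6A IP 1, 2 and 3, against 11, 13 and 9 tags for peaks found in 1 replicate. Their median fold was 5.15 against 4.54 in m6A IP 1 and 4.89 against 4.26 in m6A IP 2, but 4.47 against 4.64 in m6A IP 3, so the order of the folds was not the same in every list. Recurrence followed the −log10 q of the peak, which depends on the tag number as well as on the fold. Pooled over the lists, the median input background was 3.82 tags for peaks of regions found in all 3 replicates. For peaks found only in m6A IP 1, 2 or 3 it was 1.53, 1.68 and 0.881 tags, so input level was not held apart from strength. Of peaks with a −log10 q of at least 20, 95.6% (Wilson 95% interval 94.0 to 96.8), 95.4% (93.8 to 96.6) and 98.5% (96.5 to 99.3) lay in regions found in all 3 replicates. Of peaks with a −log10 q under 3, the shares were 27.0% (25.8 to 28.3), 24.6% (23.4 to 25.7) and 58.0% (56.6 to 59.3). The difference between strong and weak peaks, 96.5% ± 1.72 against 36.5% ± 18.6 (SD, n = 3), was larger than the spread between replicates. The higher share in m6A IP 3 came with a list shorter than the other 2.

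**Figure D1:**
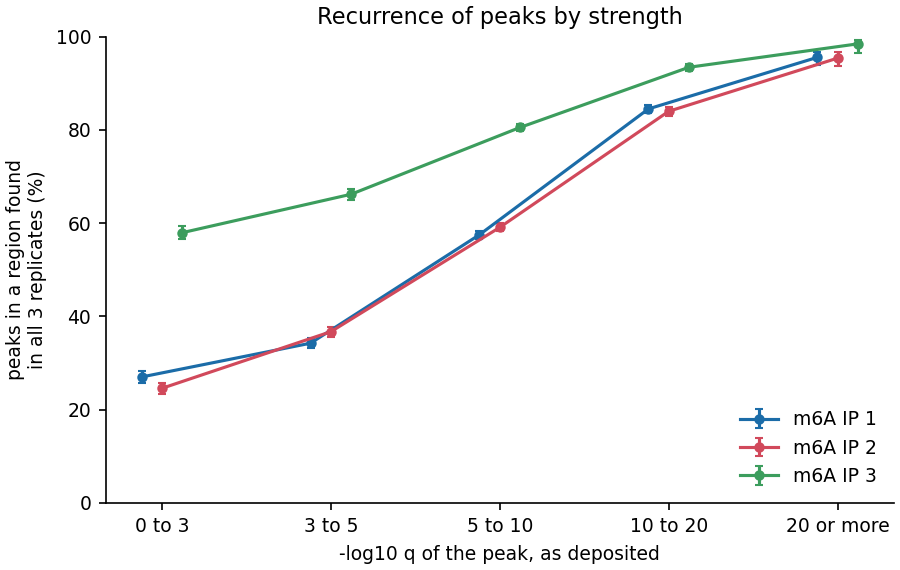
Share of peaks (percent, y axis) lying in a region found in all 3 replicates, by the deposited −log10 q of the peak (x axis). Each point is 1 replicate with its 95% Wilson interval. The share rose from 27.0%, 24.6% and 58.0% in the weakest class to 95.6%, 95.4% and 98.5% in the strongest.

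Positions were shared between replicates far more often than after a shift of 5000 bases. Averaged over the 3 pairs, 70.5% ± 2.97 of peaks (SD, n = 3 pairs) overlapped a peak of the other replicate. After the other replicate's peaks had been moved by 5000 bases, 1.56% ± 0.186 did, a ratio of 45.4 ± 3.28. Each value is the mean of both directions, which differed with list length: 80.2% and 79.8% of the peaks of m6A IP 3 overlapped m6A IP 1 and 2, against 57.7% of the peaks of either in m6A IP 3. Between m6A IP 1 and 2 the shares were 73.8% and 74.1%. The ratio depended on the distance moved: it was 10.2 for 1000 bases, where 6.92% of peaks still overlapped, and 81.8 for 50000 bases. It was 157 when an overlap of at least 50% of each peak was required. No background of expressed transcripts came with the peak lists. The ratio therefore does not separate shared enrichment from the shared placement of expressed RNA.

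The order of regions by fold was shared only in part. Across regions with peaks in both replicates, Spearman's rho of the fold was 0.663 for m6A IP 1 and 2 (23354 regions), 0.611 for m6A IP 1 and 3 (18389 regions) and 0.623 for m6A IP 2 and 3 (18317 regions). Regions are not independent replicates and no p-value was computed. The same regions gave a rho of 0.944 ± 0.0041 (SD, n = 3 pairs) for pileup and 0.893 ± 0.0078 for the local input background, so height and input level ranked more alike than their ratio. In regions found in all 3 replicates the fold had a median coefficient of variation of 20.5%, and in 25% of them it was above 30.0%. Their median pileup was 25, 25 and 22 tags over a median background of 3.82, 3.92 and 3.83 tags in m6A IP 1, 2 and 3. Counting error on so few tags also adds to this variation and lowers rho, and how much was not tested. Among peaks with a fold of at least 4, the mean rho was 0.408. That filter narrows the range of the ranked value, which can lower rho by itself.

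The 10 recurrent regions with the highest mean percentile of the deposited fold had mean folds of 17.6 to 24.1 over an input that was close to empty. The median of the mean fold over the 16757 regions found in all 3 replicates was 5.13, with quartiles of 3.90 and 6.65, and 724 regions (4.32%) reached a mean of at least 10. The region with the highest mean percentile lay on chromosome 15 from 78258925 to 78259289 (mm9), with a fold of 24.1 ± 4.67 (SD, n = 3) and a pileup of 36 ± 3.61 tags. Next came chromosome 2 from 29658216 to 29658451, with a fold of 20.2 ± 1.98, and chromosome 3 from 145421758 to 145422090, with 19.4 ± 1.56. The fourth was the longest of the 10, 722 bases on chromosome 12 from 79326779 to 79327500, with a fold of 20.9 ± 4.63. A 196-base region on chromosome 10 from 127496131 to 127496326 had a fold of 18.7 ± 2.69, and a 139-base region on chromosome 2 from 80421244 to 80421382 had 19.0 ± 3.57. The widest spread was on chromosome 18 from 35989447 to 35989651, where the folds of m6A IP 1, 2 and 3 were 22.7, 30.1 and 14.1, a mean of 22.3 ± 8.01. The others were chromosome 15 from 54903410 to 54903651 (18.9 ± 2.14), chromosome 2 from 155517884 to 155518059 (18.9 ± 3.85) and chromosome 16 from 49699436 to 49699628 (17.6 ± 0.519). The highest input background of each of these 10 regions, averaged over the replicates, lay between 0.165 and 1.22 tags. With so little input, the 1 added to both terms of the fold sets much of its size, and on chromosome 2 from 155517884 to 155518059 the background was the genome average in every replicate. Ranked by pileup over background without it, 2 of these regions stayed among the first 10, and ranked by −log10 q 5 did, so neither their order nor their place as the strongest was fixed by these data.

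The 5 longest regions, named after their values were seen, measured 1323 to 1707 bases, and their folds lay on both sides of the median of 5.13. The longest, on chromosome 7 from 106416106 to 106417812, had a fold of 3.20 ± 0.559 (SD, n = 3), and its highest background averaged 16.7 tags. On chromosome 2 from 143813930 to 143815437, a region of 1508 bases had a fold of 10.3 ± 4.36, the replicates standing at 14.4, 5.72 and 10.8. A pair of other long regions had nearly the same fold in every replicate: 2.60 ± 0.058 on chromosome 10 from 79593605 to 79594955 and 5.69 ± 0.058 on chromosome 6 from 101100520 to 101101842. Their pileups were 49.3 ± 0.577 and 30.7 ± 2.52 tags. The first is close to the 50 tags that duplicate removal leaves on 1 strand, which may set part of its agreement between replicates. On chromosome 2 from 155817130 to 155818494 the fold was 5.81 ± 0.883. The 5 regions with the highest mean pileup, also named after their values were seen, had folds of 2.06 to 4.02, below that median. Their highest backgrounds averaged 17.8 to 45.5 tags. Duplicate removal leaves at most 100 tags on both strands, so high backgrounds limit the fold that these regions could reach. A pileup of 94.3 ± 2.08 tags on chromosome 15 from 25294356 to 25294666 came with a fold of 2.21 ± 0.347, and one of 92.3 ± 3.79 tags on chromosome 1 from 174204181 to 174204287 with a fold of 2.06 ± 0.446.

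Recurrent regions were often close neighbours. Of the 16757 regions, 6130 (36.6%) had another region found in all 3 replicates within 1000 bases, and these formed 2550 clusters, 708 of them with at least 3 regions and 68 with at least 5. The cluster with the most regions held 11 within 6886 bases on chromosome 10, from 79773842 to 79780727, at mean folds of 3.0 to 6.02. Next were 10 regions within 4898 bases on chromosome 4 from 141027504 to 141032401, with folds of 3.99 to 7.34. Then came 9 regions each on chromosome 15 from 76005927 to 76012314, on chromosome 11 from 59999054 to 60004149 and on chromosome 2 from 121125984 to 121132761. The last differed from the others in its folds, 2.03 to 2.72, and in its input background of 20.9 tags. It kept 0 of its 9 regions at a fold of at least 4, and the chromosome 10 cluster kept 2 of its 11, while the other 3 clusters changed by at most 1.5 times. At a −log10 q of at least 10, each of the 5 clusters held between 0 and 2 regions. With a reciprocal overlap of at least 50%, the clusters on chromosomes 10, 4 and 15 held 5, 6 and 5 regions and the one on chromosome 2 held 1, and with lists of equal length the latter held 4. Regions in clusters had a median mean fold of 4.89 and a median background of 4.52 tags, and lone regions 5.28 and 3.61 tags. The share with a neighbour depended on the threshold: it was 24.1% for peaks with a fold of at least 4 and 7.97% for a −log10 q of at least 10. Whether neighbouring regions were separate segments or pieces of 1 enriched stretch split by peak calling was not tested.

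**Figure D2:**
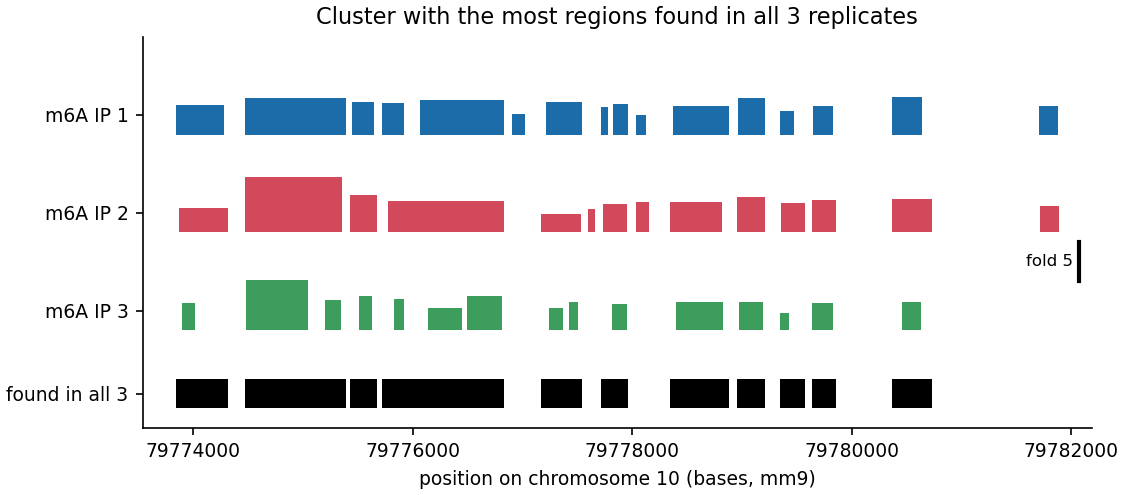
Map of the cluster on chromosome 10 (x axis, mm9 position in bases). Coloured boxes are the peaks of each replicate, with box height in proportion to the fold (scale bar, fold 5), and black boxes are the regions found in all 3 replicates, 11 of which form the cluster.

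Chromosomes differed several-fold in peak density, with chromosome 11 highest and the X chromosome lowest of the 19 autosomes and X. The Y chromosome, with at most 2 peaks in a list and 0 regions found in all 3 replicates, was left out of this comparison. The X chromosome had 5.45, 5.44 and 3.83 peaks per Mb in m6A IP 1, 2 and 3, and the 19 autosomes averaged 13.1, 13 and 9.84. No autosome was below 9.29, 8.90 and 6.58 peaks per Mb in the same lists, so X was below every autosome in each replicate. Per replicate, the density of X was 0.408 ± 0.0161 (SD, n = 3) of the autosomal mean, a gap larger than the spread between replicates. In regions found in all 3 replicates X had 409, or 2.45 per Mb, against an autosomal mean of 6.69 ± 1.83 per Mb (SD over 19 autosomes), a ratio of 0.367. The next lowest was chromosome 13 with 4.54 per Mb. Chromosome 11 had 11.5 per Mb (1398 regions), followed by chromosome 17 with 8.83, chromosome 19 with 8.36 and chromosome 7 with 8.29. Density per Mb takes no account of gene number. Per protein-coding gene of the GRCm38 annotation, chromosome 11 had 0.853 regions, against an autosomal mean of 0.799 ± 0.109 (SD over 19 autosomes). On that measure chromosome 18 was the highest at 0.984, and chromosome 7 the lowest autosome at 0.625. The median mean fold of these regions was 5.09 on X, 4.93 on chromosome 11 and 4.87 on chromosome 17, and reached 5.43 on chromosome 18. X stayed below every autosome and chromosome 11 stayed highest under each of the 8 alternatives run on the regions.

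**Figure D3:**
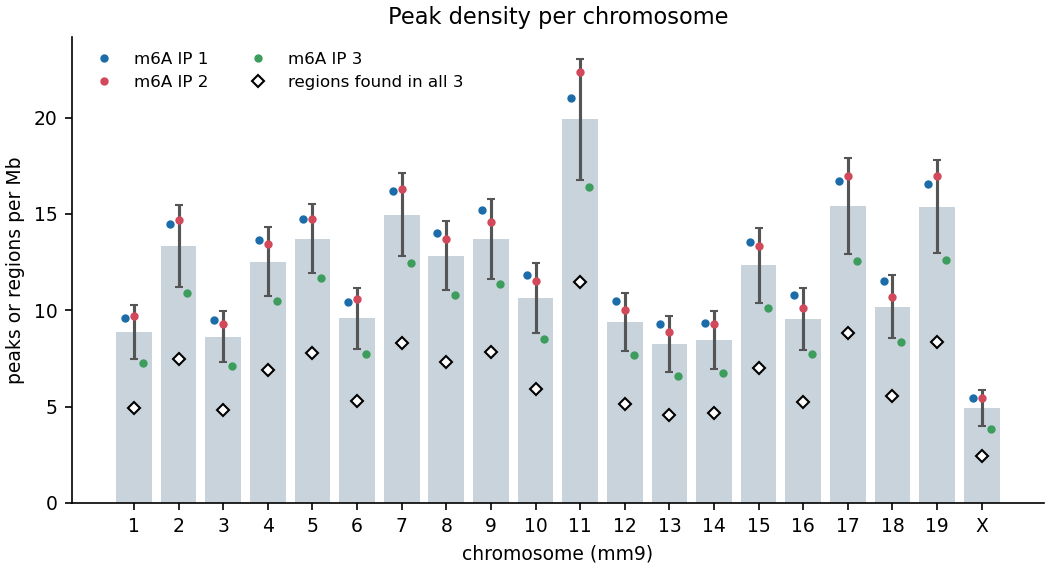
Peaks per Mb (y axis) on the 19 autosomes and X (x axis, mm9; Y is not drawn). Grey bars and whiskers are the mean and SD of the 3 replicates, coloured points the replicates, and open diamonds the regions found in all 3 replicates per Mb, which ran from 2.45 on X to 11.5 on chromosome 11.

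Fold enrichment was lower where the input was higher. Input level was compared as the number of input tags behind a peak, for peaks whose background was a whole number of tags. That background is also the denominator of the fold, so part of a fall with input level may follow from the definition. At 3 to 4 input tags the median fold was 5.17, 5.60 and 4.67 in m6A IP 1, 2 and 3, and at 17 to 32 tags it was 2.39, 2.75 and 2.20. The median fell by 2.11 times ± 0.0653 (SD, n = 3), more than the spread between replicates, while the median pileup rose from 18, 15 and 18 tags to 41, 36 and 42. From 1 input tag to 9 to 16 tags, the share of peaks in regions found in all 3 replicates rose in each list. It went from 46.9%, 39.5% and 61.3% to 65.2%, 66.0% and 89.4% in m6A IP 1, 2 and 3. At 17 to 32 tags, 95.2% (Wilson 95% interval 93.7 to 96.4) of 943 peaks of m6A IP 3 lay in regions found in all 3 replicates, against 57.9% (55.6 to 60.2) of 1759 in m6A IP 1 and 54.8% (53.3 to 56.4) of 4009 in m6A IP 2. The share was higher in m6A IP 3, the shortest list, at every input level it reached, and the tags are counted before scaling by 0.763, 0.560 and 0.881, so 1 level is not the same background in each list. At 33 to 49 tags the share was 24.1% (20.8 to 27.8) of 572 peaks in m6A IP 2 and 32.5% (23.1 to 43.5) of 77 peaks in m6A IP 1.

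**Figure D4:**
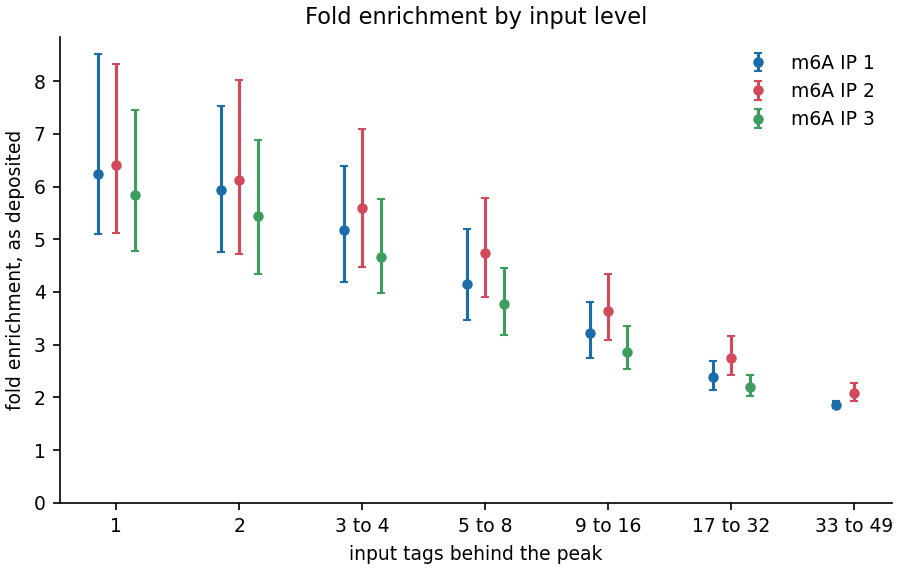
Deposited fold enrichment (y axis) by the number of input tags behind the peak (x axis). Points are medians and whiskers the quartiles over the peaks of 1 replicate, not replicate error; medians fell from 5.17, 5.60 and 4.67 at 3 to 4 tags to 2.39, 2.75 and 2.20 at 17 to 32 tags, and m6A IP 3 has no point at 33 to 49 tags, where it had under 20 peaks.

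Few peaks rose above 50 IP tags. From pileups of 46 to 50 to pileups of 51 to 55, the number of peaks fell from 570 to 72 in m6A IP 1, from 729 to 85 in m6A IP 2 and from 306 to 24 in m6A IP 3. The step just before, from 41 to 45 tags to 46 to 50 tags, was from 1206, 1471 and 726 peaks. Above 50 tags there were 134, 163 and 68 peaks, and the highest pileup was 96 tags. A pileup of 50 could reach the smallest called −log10 p only where the background was below 28.5, 28.5 and 28.1 tags. Segments with a higher background could be called only if they exceeded 50 tags. Duplicates were also removed from the inputs, where 50 tags on 1 strand scale to 38.2, 28.0 and 44.0 tags. In m6A IP 2 this lay below the callable limit, so input from 1 strand alone could not set such a background there.

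**Figure D5:**
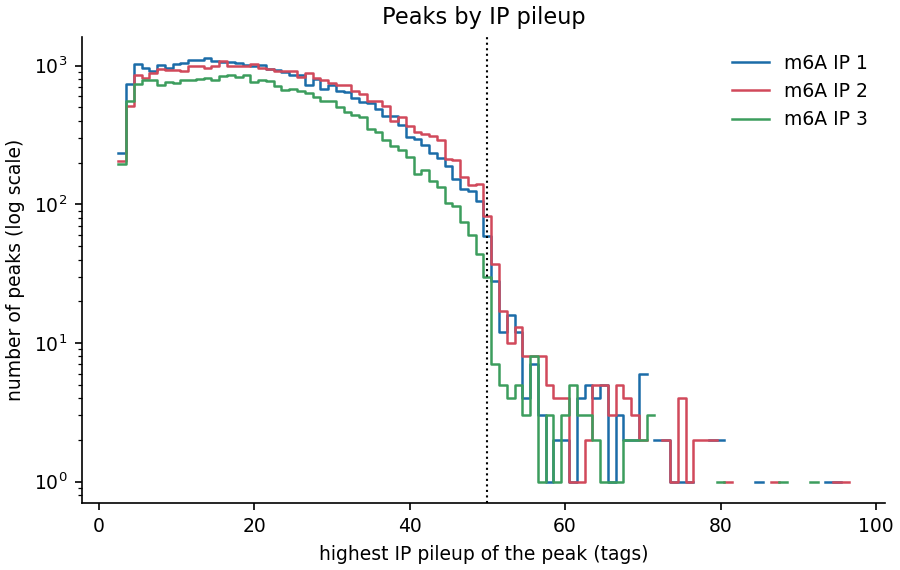
Number of peaks (y axis, log scale) at each value of the highest IP pileup in tags (x axis), for the 3 replicates. The dotted line marks 50 tags, beyond which 134, 163 and 68 peaks of m6A IP 1, 2 and 3 lay.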

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

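The X chromosome ratio, the neighbour share, the recurrence of strong peaks, the input-level fall and the named regions and clusters, with their alternatives, were chosen after seeing the data; the others before the data were examined. A stricter peak threshold removes peaks by its construction. With a fold of at least 4 the lists held 21759, 20654 and 15414 peaks and gave 8111 regions in all 3 replicates; with a −log10 q of at least 10 they held 7502, 7198 and 3766 peaks and gave 2057. Regions numbered 26546 when 2 of 3 replicates were enough and 11128 with a reciprocal overlap of 50%. Equal list lengths (13390) and leaving out 1 replicate (18549 to 23413) stayed within 1.5 times of 16757. The overlap ratio was 157 with the reciprocal overlap, 10.2 for a shift of 1000 bases and 81.8 for 50000. The mean rho of the fold was 0.408 above a fold of 4, a filter that narrows the range of the ranked value and can lower rho by itself. It was 0.523 with −log10 q as the rank, and the cause of that was not tested. The X chromosome ratio was 0.412 with 2 of 3 replicates and 0.376 to 0.403 without 1 replicate, always below 1. The neighbour share was 24.1% above a fold of 4, 7.97% above a −log10 q of 10, 32.1% at equal list lengths, 43.7% with 2 of 3 replicates, 38.9% to 42.1% without 1 replicate, and 29.2% and 42.2% for gaps of 500 and 2000 bases. Strong peaks recurred in 85.1% with the reciprocal overlap and 97.4% to 98.9% without 1 replicate. The input-level fall was 2.68 without a pseudocount. The folds of named regions were not tested for stability, since the thresholds cannot change the fold of a kept region and leaving out 1 of 3 values moves a mean by less than its SD. The long region on chromosome 10 was split when merged without m6A IP 2, and its fold was then 2.49. Of the named regions, a fold of at least 4 removed all 5 highest-pileup and 2 of the 5 longest, a −log10 q of at least 10 removed 4 of each, and the reciprocal overlap 1 of the longest; the 10 strongest could not be lost to the thresholds, having been picked for their folds. Of 40 cluster counts, 28 stayed within 1.5 times and 12 fell further. Without a pseudocount, 2 of the 10 strongest regions ranked in the first 10, and 5 by −log10 q. No paired analysis was possible because no result came from a test of IP against input libraries: folds and p-values had been made within each replicate, and pileups were given only at called peaks. The gene-level alternatives were not run, since no gene names were used here. Depth limits single peaks: 19 tags allow 11.4 to 29.7.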

Other observations

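Recurrent regions were spread unevenly over the genome. Of 2649 windows of 1 Mb, 594 (22.4%) held no region found in all 3 replicates, while 207 windows (7.81%) with at least 20 regions held 6246 regions, 37.3% of the total. The window with the most, chosen after its value was seen, was chromosome 18 from 37000001 to 38000000 (mm9) with 90 regions, followed by chromosome 10 from 79000001 to 80000000 with 77, which contains the cluster of 11 regions, and chromosome 7 from 134000001 to 135000000 with 73. Next were the adjoining window of chromosome 10, from 80000001 to 81000000, with 70, and chromosome 15 from 76000001 to 77000000 with 60.

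The low density on X was also present relative to gene number. Counted per protein-coding gene on each chromosome in the GRCm38 annotation, used only for gene numbers and not for positions, X had 0.431 regions found in all 3 replicates per gene, against a mean of 0.799 ± 0.109 (SD over 19 autosomes) and a lowest autosomal value of 0.625 on chromosome 7. In peaks, X had 0.863 ± 0.164 per gene (SD, n = 3) and the autosomes 1.43 ± 0.192 (SD over 19). The expression of X-linked genes was not measured here, so the value is not a rate per expressed gene. The Y chromosome had 1 peak in m6A IP 1, from 1217395 to 1217444, and 2 in m6A IP 2, from 1217402 to 1217451 and from 2461440 to 2461505, with pileups of 10, 7 and 7 tags. It had none in m6A IP 3. No list held a peak on the mitochondrial chromosome.

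All tests of the 3 patterns weighed here were chosen after the result they measure had been seen, except the test of lower folds in m6A IP 3 and the test on the top 5% of peaks. The test at a fold of at least 3 replaced one at a fold of at least 4, which gave no value because m6A IP 3 had 0 such peaks at 17 to 32 input tags, and its requirement that 95% of the chosen regions be called again was added after its values were seen. No biological explanation was tested, since the samples formed 1 condition.

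The list of m6A IP 3 was the shortest, with 24686 peaks. Lower IP depth is argued against, since m6A IP 3 had 1.11 times the filtered IP tags of m6A IP 1, which had 32858 peaks. Greater loss to duplicates is also argued against, as its redundant rate of 0.63 was below the 0.66 and 0.65 of the others. Weaker enrichment at the same places may account for it: in 48.0% of regions found in all 3 replicates the fold was lowest in m6A IP 3, against 23.9% and 28.1% for m6A IP 1 and 2, and its median pileup there was 3.48 per 1000000 filtered IP tags against 4.40 and 3.85. Whether that came from the antibody step or from the RNA stays open.

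The scarcity of peaks above 50 tags is consistent with duplicate removal, which leaves at most 50 tags of 50 bases over a base on 1 strand. The fall in peak number across a pileup of 50 was at least 3.74 times as steep as the fall just before it in every replicate. The highest pileup, 96 tags, lay below the 100 that both strands would allow.

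The fall of the fold with input level could come from the calling threshold, which asks a higher fold of peaks over low input, or from duplicate removal, which holds pileups near 50 tags over high input. Among peaks with a fold of at least 3 in 1 replicate, the median fold in another replicate fell by 1.33 to 1.95 times over 6 ordered pairs, the lowest resting on 17 high-input regions, but a fold of 3 was not callable at every input level and as few as 64.0% of the low-input regions were called in the second replicate, so the threshold is not excluded. An earlier test on the top 5% of peaks gave falls of 1.91 to 2.45 times, past the bound of 1.5 set for it, but that bound was wrong, because the top of a list moves with the threshold of the list. After tags before duplicate removal were estimated on the assumption of uniform starts on 1 strand, the median still fell by at least 1.88 times, but that assumption is untested. The input background is also the denominator of the fold, and how much of the fall follows from that was not tested. The explanations cannot be told apart from peak lists alone.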
